A study of Mus musculus with 9 samples.

How the data were processed

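Plantaris muscle, a fast hindlimb muscle, was taken from 3-month-old male C57BL/6J mice after 0, 2 or 6 h in 8% oxygen, per the labels' protocols. Each time point has 3 libraries, so 9 libraries entered the comparisons. Groups and replicate numbers were read from the sample titles. The animals were killed at the end of exposure, so the groups hold different animals. The labels do not say outright that each library is a separate mouse, and p-values measure the spread between these libraries. Paired-end TruSeq RNA libraries were sequenced on an Illumina instrument, per the labels.

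The submitters' processing notes name FastQC, TopHat2, Bowtie2, SAMtools and bedtools, without versions, and the mouse genome build mm9. The tool that turned alignments into gene values and its use of strand are not given in the sources used here. The deposited table holds 13722 genes. Its values per library are RPKM as made by the authors (reads scaled by exon length and library total), a unit recognised from the values. The deposited table also gives the largest raw read count of each gene over the libraries, the authors' fold changes against control, and the authors' raw and adjusted p-values, whose test is not stated in the sources used here. Coordinates are those of the file. A later annotation, GRCm38, shared 13265 of the gene identifiers but only 629 lay within 1000 bases at both ends, so no coordinate was taken from it.

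Low RPKM values move in steps that depend on gene and library. These steps returned whole reads, within 0.1 read, for 100% of the 40179 values below 500 reads, and each value stands for its reads plus 1. In all 384 genes with a repeated lowest value, the largest recovered count equalled the deposited one. The other genes were scaled by the deposited largest count, so it tests nothing there. The recovered totals were 124371305, 109220427 and 117684235 reads for control replicates 1 to 3, 116013788, 127765992 and 137097898 at 2 h, and 114490718, 106493351 and 72706716 at 6 h. These totals lie mostly above the range of reads per sample given in the labels, so a counted read may be a mate of a pair or be counted in more than 1 gene, and the totals describe relative depth. The values of a library with 0 reads sit at a small fixed value of that gene, and no value in the table is exactly 0.

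Each comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), with a mean-variance trend, over all 9 libraries and with group means alone. Genes with a mean RPKM of at least 0.5 were tested, 13309 in all. Adjusted p-values are Benjamini-Hochberg values within a comparison, with a threshold of 0.05. A fold change is on the log2(RPKM + 0.5) scale and understates the change of genes near that level. The contrasts were 2 h against control, 6 h against control and 6 h against 2 h. Because the 3 controls serve both times, the overlap was set beside 100 simulations of unchanged groups, with each gene varying on its own, and beside the overlap of independent lists. Of 34 gene lists fixed before the data were examined, 33 had at least 3 tested members and were tested with camera at a preset correlation of 0.01, adjusted over 99 tests. The lymphocyte list had 1 tested member. Camera with an estimated correlation was run beside it.

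Data were simulated with the real means and spread, each gene varying on its own. The fit of 13309 genes recovered 70%, 76% and 76% of genes changed 2-fold at 2 h against control, 6 h against control and 6 h against 2 h. It recovered 32%, 32% and 28% of genes changed 1.5-fold in those comparisons. It called 12, 12 and 6 unchanged genes.

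The genes named are, per comparison, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, some of the 4 members of each list with the smallest p, and 25 genes chosen beforehand for hypoxia, glucocorticoid, clock, FoxO, heat shock and cold responses. Predicted genes and genes without symbols were left out of the first part, and Gm16983, Gm17345 and 6430548M08Rik are named because they differed between the times. Tfrc is also named in comparisons where the rule does not name it, after its values were seen. 1 gene of the first part is not reported here. Alternatives set before the data were examined changed the pseudocount, the filter, the scaling, the variance model, library weights, the libraries in the fit, the replicate number as a block, a fold threshold and each library in turn. Added after the data were seen were a fit without the 3 libraries described in the report, a fit with a term for them, edgeR 4.0.16 quasi-likelihood tests and DESeq2 1.42.0 tests on the recovered reads, and list tests without each library. None of the 36 pairs of libraries agreed within counting noise (chi-square per gene between 66.6 and 470.7), so none was taken for a duplicate. Genes with values of their own in the text that overlap another annotated gene are named as such, since reads may be shared between them.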

Results

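The study asked how skeletal muscle of the living mouse changes its gene expression when the animal breathes 8% oxygen for a few hours. Transcripts of the plantaris muscle were measured by RNA sequencing in 3 groups of 3 libraries: control mice, mice after 2 h of hypoxia and mice after 6 h of hypoxia. A single control group, at 0 h, serves both times. Changes with exposure thus cannot be told apart from other changes over those hours, such as clock time or handling. The reads recovered per library ranged from 72706716 in 6 h replicate 3 to 137097898 in 2 h replicate 3. The 10 most abundant genes took between 20.9% and 24.6% of the reads of a library. All values are RPKM, given as mean ± SD over 3 libraries, and fold changes carry the standard error of the limma fit.

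Some differences between libraries ran across the groups. Control replicates 2 and 3 and 6 h replicate 2 had high levels of matrix and macrophage genes. Postn, a secreted matrix protein, stood at 37.4, 21.9 and 43.2 RPKM in these 3 libraries and between 1.32 and 3.45 RPKM in the other 6. All 22 tested collagen and matrix genes, and 12 of 13 macrophage markers, were higher in each of the 3 than in each of the other 6, whereas this held for 0 of 13 endothelial markers. The first principal component, with 37.3% of the variance, set these 3 libraries apart from the rest. Slow fibre genes were high in 6 h replicate 3, where Myh7, the slow myosin heavy chain, reached 170 RPKM and Tnni1, slow troponin I, 419 RPKM. In 6 h replicate 2 these stood at 29.2 and 65.4 RPKM. In 6 h replicate 1 Mbp, a myelin protein, stood at 213 RPKM, against 12.8 to 24.0 RPKM elsewhere. Ttr, the thyroid hormone carrier transthyretin, reached 1494 RPKM in 2 h replicate 2 and 21.1 RPKM in 2 h replicate 3, and was below 1 RPKM in the other 7 libraries.

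**Figure D1:**
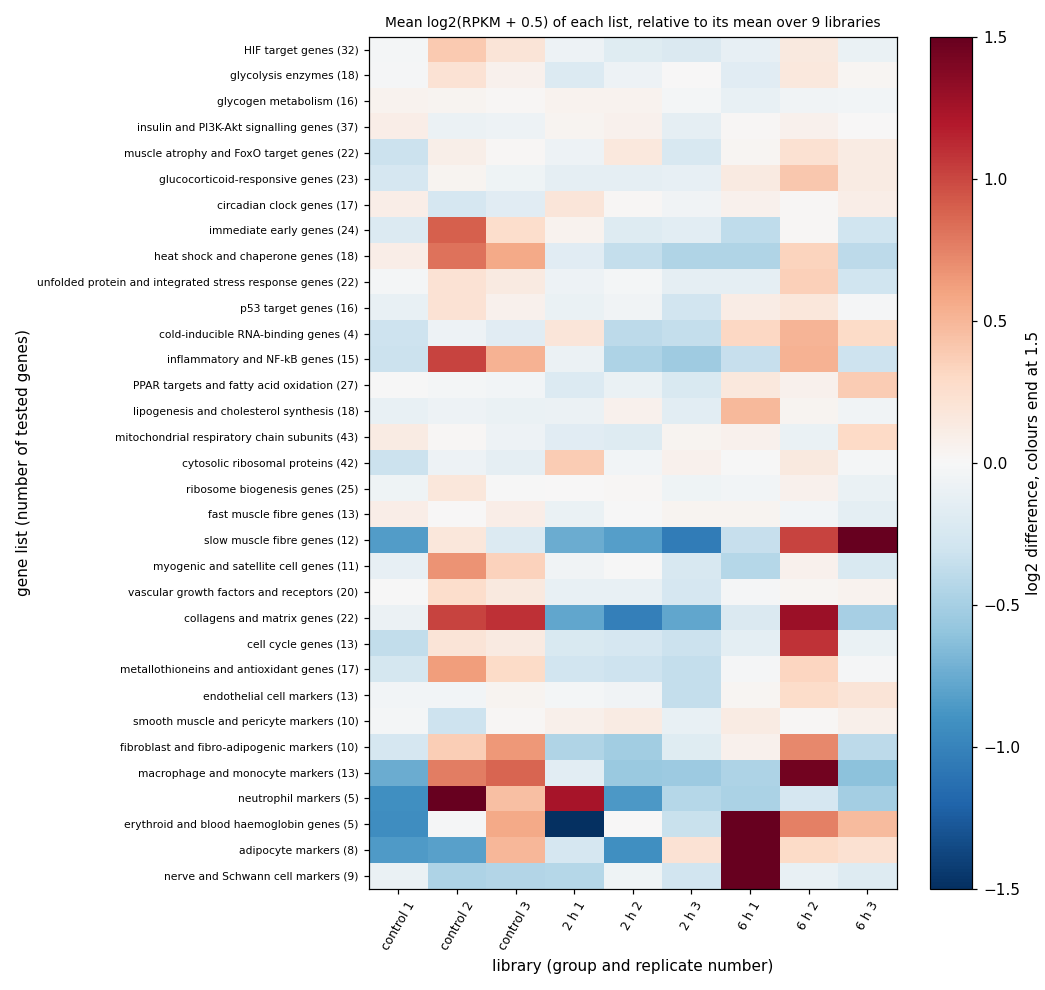
Mean log2(RPKM + 0.5) of each gene list in each of the 9 libraries, relative to the mean of the list over all libraries; each row is a list with its number of tested genes, each column a library. Collagen and matrix genes stand high in control 2, control 3 and 6 h replicate 2, and slow fibre genes in 6 h replicate 3.

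The comparison of 2 h with control asked which transcripts respond early. After 2 h, 63 genes rose and 40 fell among the 13309 tested. Foxo1, a transcription factor restrained by insulin signalling, rose 2.24-fold, from 4.83 ± 0.350 to 11.6 ± 2.27 RPKM (log2 1.17 ± 0.14 SE, adjusted p = 0.0197). Pik3ip1, an inhibitor of PI3 kinase, rose from 10.4 ± 0.885 to 22.5 ± 1.96 RPKM (log2 1.08, adjusted p = 0.0145). Tfrc, the transferrin receptor that brings iron into cells, fell from 54.0 ± 20.1 to 11.9 ± 2.35 RPKM (log2 -2.09, adjusted p = 0.0197). Hes1, a repressor downstream of Notch, fell from 18.2 ± 2.41 to 6.13 ± 0.613 RPKM (log2 -1.49, adjusted p = 0.0197). Foxo1 lies on chromosome 3 from 52072259 to 52154031 and Hes1 on chromosome 16 from 30064470 to 30067882 in mm9. Foxo1, Pik3ip1 and Cry2 each overlap another annotated gene on the opposite strand.

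The other large rises at 2 h were those of Asb15, a muscle ubiquitin ligase subunit (log2 2.11), Inmt, a methyltransferase (1.92), Cys1 (1.47), Acvr1b, an activin receptor (1.21), the nuclear noncoding RNA Neat1 (1.13), the glutathione transferase Gstm1 (1.11), Klf15, a transcription factor induced by glucocorticoids (1.06), and Amy1 (1.02), which overlaps Rnpc3. The other large falls were those of Azin1, a regulator of polyamine synthesis (-1.62), Relt (-1.48), the phosphatase Dusp10 (-1.36), Ccdc69 (-1.28), Slc22a3 (-1.27), Mum1l1 (-1.26), Bace1 (-1.13), which overlaps Rnf214 on the opposite strand, and Kdr, a VEGF receptor (-1.12). The adjusted p of these 16 genes by limma lay between 0.0210 and 0.0486. Slc22a3 averaged 0.137 RPKM at 2 h, below the pseudocount. Mum1l1 at 2 h (0.563 RPKM) and Cys1 in control (0.634 RPKM) lay close to it.

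Single genes of the insulin and PI3K-Akt, atrophy and FoxO, glucocorticoid and clock lists rose at 2 h, and none of these 4 lists passed camera as a group (adjusted p = 0.784, 0.179, 0.351 and 0.0555). Of 37 tested insulin and PI3K-Akt genes 2 rose, Foxo1 and Pik3ip1, and 0 fell; adjusted over the list alone, 7 rose and 4 fell. Of 22 atrophy and FoxO target genes Foxo1 and Klf15 rose, with 7 rising and 2 falling adjusted over the list alone. Of 23 glucocorticoid-responsive genes Klf15 and Arrdc2 (log2 0.99) rose and 0 fell; adjusted over the list alone, 7 rose and 2 fell. Of 17 clock genes Cry2 rose (log2 0.64, adjusted p = 0.0210 by limma), and 9 rose and 4 fell when adjusted over the list alone. Of 32 hypoxia-inducible factor targets 0 passed, and 3 rose and 4 fell adjusted over the list alone. Their median log2 was -0.29 and the list tested lower as a group (camera adjusted p = 0.0369; adjusted p = 0.801 with an estimated correlation). Vegfa, a growth factor for blood vessels, stood at log2 -0.58 (adjusted p = 0.0984 by limma), Slc2a1 at -0.45, Ldha at -0.34, Hif1a at -0.53 and Epas1 at 0.22, none of which passed over all genes tested; adjusted over the list alone, Vegfa passed (adjusted p = 0.0389). Slc2a1, Hif1a and Epas1 each overlap another annotated gene, Epas1 on the same strand.

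Of the 25 genes chosen beforehand, Foxo1 was called at 2 h by limma. The fit with a term for the 3 libraries of high matrix genes called 0 of them, edgeR 1 and DESeq2 10. Fbxo32, an atrophy ubiquitin ligase, stood at log2 1.04 (74.98 ± 14.7 RPKM in control and 159.6 ± 56.6 at 2 h, adjusted p = 0.0833), and Trim63, another such ligase, at 0.39. The glucocorticoid-induced genes Fkbp5 and Tsc22d3 stood at 1.07 and 0.55 (adjusted p = 0.0704 and 0.0569). The metallothioneins Mt1 and Mt2, which bind zinc, stood at -1.74 and -2.36 (adjusted p = 0.207 and 0.133); both were higher in control replicates 2 and 3 than in control replicate 1 and the 2 h libraries. Adjusted over the list alone, Fbxo32, Fkbp5, Tsc22d3 and Mt2 passed. Cirbp stood at 0.59, Dbp at 0.59, Pik3r1 at 0.48, Per1 at 0.26, Pdk4 at 0.25, Pdk1 and Irs2 at -0.06 each, Rbm3 at -0.27, Ddit4 at -0.28, Myc at -0.41, Cdkn1a at -0.81 and Angptl4 at -0.82, with adjusted p between 0.175 and 0.890. Fbxo32, Dbp, Irs2, Ddit4 and Angptl4 each overlap another annotated gene.

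Some lists shifted together at 2 h with few or no members past the test of single genes. All 18 heat shock and chaperone genes had lower means, with a median log2 of -0.76 (camera adjusted p = 1.49e-07), and 11 fell when adjusted over the list alone. Hspa8 stood at -1.28 and Hspa1b at -1.99. With a term for the 3 libraries of high matrix genes the heat shock median was -0.266. All 22 collagen and matrix genes had lower means, with a median of -1.48 (adjusted p = 1.17e-10), and 17 fell adjusted over the list alone; these are the genes that were high in control replicates 2 and 3, and the heat shock mean was also highest in those 2 libraries. All 42 ribosomal protein genes had higher means, with a median of 0.31 (adjusted p = 4.98e-11), and 4 rose adjusted over the list alone; their mean was lowest in control replicate 1 and highest in 2 h replicate 1. With an estimated correlation the adjusted p of each of these lists was 0.801. The lists of inflammatory, respiratory chain, vascular, metallothionein and antioxidant, immediate early and glycolysis genes also tested lower (adjusted p between 0.00142 and 0.0369; 0.801 to 0.832 with an estimated correlation). In these 6 lists 1 gene fell, Kdr, and 1 rose, the plasma glutathione peroxidase Gpx3 (log2 0.86). Adjusted over the list alone, 6 metallothionein and antioxidant, 3 vascular, 3 glycolysis, 1 inflammatory and 1 immediate early gene fell, and 1 glycolysis gene and Gpx3 rose. Without the 3 libraries of high matrix genes the heat shock, matrix, ribosomal protein and respiratory chain lists still passed camera. The hypoxia-inducible factor target, glycolysis, immediate early, inflammatory, metallothionein and vascular lists did not. That fit keeps control replicate 1 as the only control. Its ribosomal protein mean was the lowest of all libraries (-0.323 from the list mean on the log2 scale). Its respiratory chain mean was the highest of the controls (0.122). A pass there rests on that library and adds no support.

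All 103 genes called at 2 h had groups that did not overlap, which held for 27.5% of all tested genes, against 10% by chance. The count of 103 rested on single libraries. It was 0 without control replicate 2, without control replicate 3 or without 2 h replicate 2, where limma gave 2038, 1726 and 2264 genes at unadjusted p under 0.05. It was 13 without 2 h replicate 1, 11 without 2 h replicate 3, 30 without 6 h replicate 1, 18 without 6 h replicate 3, 160 without control replicate 1 and 396 without 6 h replicate 2. With a term for the 3 libraries of high matrix genes it was 6, and without those libraries 0, with 1578 genes at unadjusted p under 0.05 by limma. The term marks control replicates 2 and 3 and no 2 h library, so it overlaps with this contrast. With the term 2398 genes had an unadjusted p under 0.05 by limma, against 2678 in the reported fit. In the drop to 6, lost precision and the matrix pattern cannot be told apart. The authors' deposited table had no gene at an adjusted p under 0.05 at 2 h and 2624 at a raw p under 0.05. On the recovered reads edgeR called 186 genes and DESeq2 1406. The split of 63 rises and 40 falls turned to 58 and 66 with only the groups compared in the fit, 12 and 17 without the mean-variance trend, 1517 and 1551 with library weights, 73 and 87 without control replicate 1, 4 and 7 without 2 h replicate 3, and 2 and 4 with the term.

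**Figure D2:**
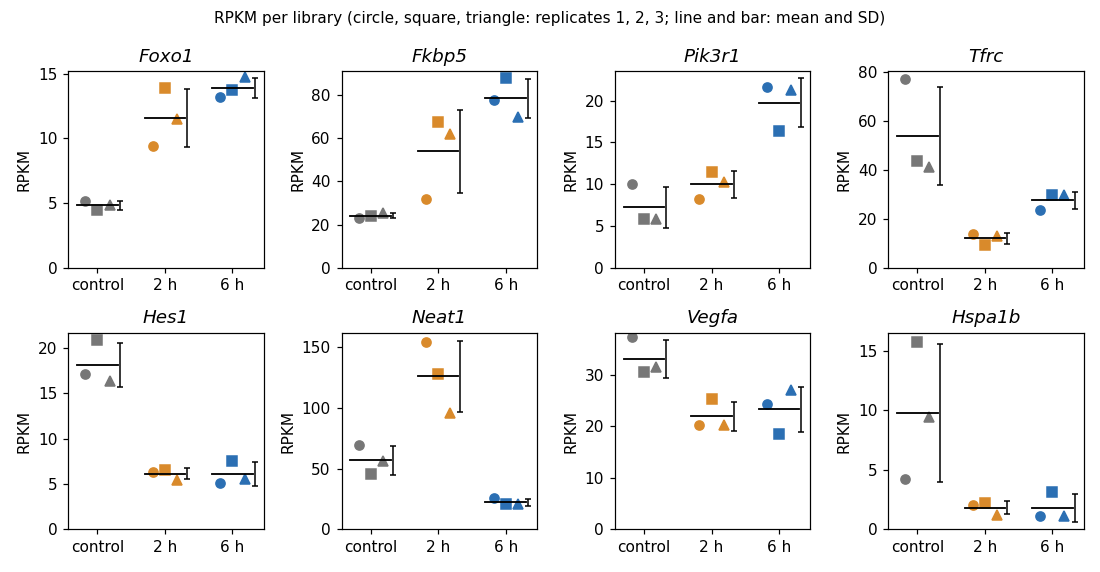
RPKM of 8 genes in each library by group; circles, squares and triangles are replicates 1, 2 and 3, the line is the mean and the bar the SD. Foxo1 rises from a mean of 4.83 to 11.6 and 13.9 RPKM, and Neat1 is high at 2 h and low at 6 h. In the reported fit the lower means of Vegfa and Hspa1b did not pass limma over all genes tested at either time.

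After 6 h, compared with control to show the later response, 133 genes rose and 80 fell. Foxo1 rose 2.70-fold to 13.9 ± 0.769 RPKM (log2 1.43 ± 0.14 SE, adjusted p = 0.00651). Fkbp5, a chaperone of the glucocorticoid receptor that glucocorticoids induce, rose from 24.2 ± 1.19 to 78.6 ± 9.11 RPKM (log2 1.68, adjusted p = 0.0229). Pik3r1, the regulatory subunit of PI3 kinase, rose from 7.22 ± 2.46 to 19.8 ± 2.92 RPKM (log2 1.43, adjusted p = 0.0243); it overlaps Gm11016 on the opposite strand. Pde4b, a cyclic AMP phosphodiesterase, fell from 20.0 ± 7.42 to 3.12 ± 0.612 RPKM (log2 -2.46, adjusted p = 0.0101). Myod1, a master regulator of muscle cells, fell from 10.3 ± 6.56 to 2.13 ± 0.292 RPKM (log2 -1.88, adjusted p = 0.0386).

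The other large rises at 6 h were those of Pnmt, the enzyme that makes adrenaline (log2 1.86), Dgat2, which makes triglycerides (1.82), Inmt (1.75), Amotl2 (1.59), Doc2b (1.56), Acvr1b (1.45) and Abca1, a cholesterol exporter (1.45). The other large falls were those of Dysfip1 (-1.66), Mterf (-1.57), Hes1 (-1.51), Dusp10 (-1.48), Ccdc69 (-1.47), Cpeb1 (-1.34), the zinc transporter Slc39a10 (-1.34) and Neat1 (-1.32). The adjusted p of these 15 genes by limma lay between 0.00651 and 0.0438. Doc2b averaged 0.252 RPKM in control, below the pseudocount. Mterf, Slc39a10 and Ccdc69 averaged 0.570, 0.562 and 0.645 RPKM at 6 h, close to it.

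Glucocorticoid-responsive and clock genes were among the genes that changed at 6 h. Of 23 glucocorticoid-responsive genes 5 rose, namely Fkbp5, Pik3r1, Per1 (log2 1.00), Sult1a1 (0.94) and Fam107a (1.12), and Ddit4 fell (-0.76). Adjusted over the list alone, 10 rose and 4 fell. Of 17 clock genes 3 rose, namely Per1, Cry2 (log2 0.80) and Usp2 (0.70), with 8 rising and 5 falling adjusted over the list alone. Of 37 insulin and PI3K-Akt genes 4 rose, Foxo1, Pik3r1, Sesn1 (0.82) and Pik3ip1 (0.52), and 2 fell, Ddit4 and Trib1 (-0.94); adjusted over the list alone, 5 rose and 5 fell. Of 22 atrophy and FoxO target genes Foxo1 and Sesn1 rose, with 6 rising and 2 falling adjusted over the list alone. None of these 4 lists passed camera, whose adjusted p lay between 0.183 and 0.954. The atrophy ligases Fbxo32 and Trim63 stood at log2 -0.07 and -0.01 at 6 h, against 1.04 and 0.39 at 2 h, none of them called. Cirbp, an RNA-binding protein induced by cold, rose from 19.6 ± 0.334 to 45.3 ± 2.81 RPKM (log2 1.18, adjusted p = 0.0353 by limma), and Rbm3, another such gene, stood at 0.48. Sult1a1, Usp2, Ddit4, Pik3ip1, Cry2, Rbm3 and Fbxo32 each overlap another annotated gene. Ucp3, a mitochondrial uncoupling protein, rose (log2 1.00, adjusted p = 0.0488 by limma).

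Of 32 hypoxia-inducible factor targets Ddit4 fell and 0 rose, and adjusted over the list alone 3 fell. Their median log2 was -0.139, and the list did not pass camera at 6 h (adjusted p = 0.0542). Vegfa stood at log2 -0.51 (adjusted p = 0.137 by limma), Slc2a1 at -0.28, Ldha at -0.12 and Pdk1 at 0.15. With a term for the 3 libraries of high matrix genes, which makes p-values too small, Vegfa (log2 -0.63, adjusted p = 0.0334 by limma) and the heat shock gene Hspa1b (-1.68, 0.0158) were called lower at 6 h, and Pdk4, a kinase that restrains pyruvate oxidation, higher (0.73, 0.0365). In the reported fit Hspa1b stood at -2.12 (adjusted p = 0.0585) and Pdk4 at 0.64 (0.0709). Of the other genes chosen beforehand Dbp stood at 0.74, Mt2 at 0.62, Angptl4 at 0.62, Epas1 at 0.44, Mt1 at 0.41, Cdkn1a at 0.22, Irs2 at 0.03, Tsc22d3 at -0.15, Hif1a at -0.30 and Myc at -0.41 (adjusted p between 0.199 and 0.943). Adjusted over the list alone, Pdk4, Dbp and Hspa1b passed. Heat shock genes tested lower as a group, with 17 of 18 means below control and a median log2 of -0.47 (camera adjusted p = 3.32e-07), and 7 fell adjusted over the list alone. The list mean in 6 h replicate 2 was above that of control replicate 1, and with the term the heat shock median was -0.314. Immediate early genes tested lower (median -0.45, adjusted p = 0.000101), with Zfp36, which destabilises inflammatory mRNAs, at log2 -1.21 (adjusted p = 0.0240 by limma) and 3 falling adjusted over the list alone. Matrix, myogenic and inflammatory lists also tested lower (camera adjusted p = 0.00416, 0.00478 and 0.0199), with 3 myogenic genes falling and 1 rising adjusted over the list alone. The matrix mean was the highest of all libraries in 6 h replicate 2 (1.284 from the list mean on the log2 scale). The myogenic, inflammatory and immediate early means were highest in control replicate 2 (0.669, 1.014 and 0.9). In control replicate 1 (-0.126, -0.327 and -0.203) these means lay below those of 6 h replicate 2 (0.061, 0.526 and 0.021). Ribosomal protein genes tested higher (median 0.22, adjusted p = 0.000101), as did the slow fibre, nerve and Schwann cell, and cold-inducible lists (adjusted p = 0.00569, 0.0331 and 0.0418). With an estimated correlation the adjusted p was 0.801 for each of these 9 lists. The slow fibre list had a mean log2 of 1.46 and none of its 12 members passed, adjusted over the list alone or over all genes; the list mean was high in 6 h replicates 2 and 3 and not in 6 h replicate 1. The nerve list was high in 6 h replicate 1. Without the 3 libraries of high matrix genes the heat shock, ribosomal protein and slow fibre lists still passed camera and the other 6 did not. That fit keeps control replicate 1 as the only control. Its ribosomal protein and slow fibre means were the lowest of the controls (-0.323 and -0.834 from the list means on the log2 scale). A pass there rests on that library and adds no support.

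All 213 genes called at 6 h had groups that did not overlap, as did 25.9% of all genes (10% by chance). The count was 25 without control replicate 2, 15 without control replicate 3, 18 without 6 h replicate 1, 10 without 6 h replicate 3, 110 without 2 h replicate 2, 101 without 2 h replicate 3 and 417 without 6 h replicate 2; without all 3 libraries of high matrix genes, which leaves 1 control, it was 0, with 1649 genes at unadjusted p under 0.05 by limma. With a term for those libraries it was 374. Medians set equal between libraries gave 111 rises and 131 falls in place of 133 and 80, quantile normalization 122 and 155, edgeR 127 and 202, DESeq2 508 and 620, and leaving out 6 h replicate 2 gave 205 and 212. Foxo1, Hes1, Amotl2, Cpeb1, Cry2 and Pitx3 (log2 1.02) were called in every alternative except the one that left the 3 libraries out. The authors' deposited table had 6 genes at an adjusted p under 0.05 at 6 h, of which 5 were higher and 1 lower; edgeR called 329 genes in all and DESeq2 1128.

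The comparison of 6 h with 2 h tested whether the exposure times differ. At 6 h 9 genes stood higher and 10 lower than at 2 h. Neat1, an RNA that builds nuclear paraspeckles, had risen at 2 h and was below control at 6 h, with 57.0 ± 11.9 RPKM in control, 126 ± 29.3 at 2 h and 22.3 ± 2.79 at 6 h (log2 -2.45 ± 0.20 SE for 6 h against 2 h, adjusted p = 0.00865). It lies on chromosome 19 from 5824708 to 5845480 in mm9. D4Wsu53e was lower at 6 h (log2 -1.39, adjusted p = 0.0312), as were Tmem100 (-1.14), B3galnt2 (-1.09), Clec2d (-0.74), Mettl3, an RNA methyltransferase (-0.64), and Actr6 (-0.61). Mtss1 (1.13), Amotl2 (1.08), Fam117b (0.87), Abhd1 (0.85), Jup (0.83), the transcription factor Pitx3 (0.77), Tpst2 (0.72) and Acsl1, an acyl-CoA synthetase (0.69), were higher. B3galnt2, Mettl3 and Abhd1 overlap genes on the opposite strand.

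In the lists that tested as a group between 6 h and 2 h, no member passed over all genes tested by limma. Matrix (median log2 1.00, adjusted p = 1.57e-05), slow fibre (2.11, 4.29e-05), respiratory chain (0.19, 0.000462) and fatty acid oxidation genes (0.31, 0.000519) tested higher at 6 h by camera, as did erythroid, endothelial, cell cycle, cold-inducible and adipocyte lists (adjusted p between 0.00416 and 0.0315). Adjusted over the list alone, 9 of 12 slow fibre and 5 of 27 fatty acid oxidation genes rose, as did 5 of 5 erythroid, 5 of 13 endothelial, 3 of 4 cold-inducible and 1 of 8 adipocyte genes, and none of the matrix, respiratory chain and cell cycle genes. Ribosomal protein (-0.11, adjusted p = 0.00142) and glycogen genes (-0.11, 0.0315) tested lower, with 3 glycogen genes falling adjusted over the list alone. With an estimated correlation the adjusted p was 0.801 for each. Matrix and cell cycle genes were high in 6 h replicate 2, slow fibre genes in 6 h replicates 2 and 3, respiratory chain genes in 6 h replicate 3, and haemoglobin and adipocyte genes in 6 h replicate 1, while haemoglobin genes were low in 2 h replicate 1. Without the 3 libraries of high matrix genes the cell cycle, cold-inducible and glycogen lists no longer passed camera (adjusted p = 0.310, 0.0642 and 0.181).

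Of the 25 genes chosen beforehand, 0 were called between 6 h and 2 h by limma and 13 had an unadjusted p under 0.05; edgeR called 1, DESeq2 10 and the fit with a term for the 3 libraries 3. Mt2 stood at log2 2.99 (adjusted p = 0.121), Mt1 at 2.16, Angptl4 at 1.44, Cdkn1a at 1.03, Pik3r1 at 0.95, Rbm3 at 0.75, Per1 at 0.73, Fkbp5 at 0.61, Cirbp at 0.60, Ddit4 at -0.48, Tsc22d3 at -0.70 and Fbxo32 at -1.11 (adjusted p = 0.115). The other 13 lay between -0.40 for Trim63 and 0.39 for Pdk4. Adjusted over the list alone, Mt2, Angptl4, Pik3r1, Rbm3, Per1, Cirbp, Tsc22d3 and Fbxo32 passed in each list that holds them, and Mt1 and Ddit4 passed in the glucocorticoid list. With the term Mt2 (2.28), Pik3r1 (1.14) and Tsc22d3 (-0.75) were called.

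The count of 19 was 0 without 2 h replicate 2 or 6 h replicate 3, with 1756 and 2165 genes at unadjusted p under 0.05 by limma, and 1 without 2 h replicate 3 or 6 h replicate 1. It was 2 without control replicate 2 or control replicate 3, 4 without 6 h replicate 2, 7 without 2 h replicate 1 and 9 without control replicate 1. Without the 3 libraries of high matrix genes it was 2, and with a term for them 99. Medians set equal gave 18 higher and 33 lower, quantile normalization 3 and 12, edgeR 20 and 44, and DESeq2 891 genes in all, in place of 9 and 10. Higher genes outnumbered lower ones with the term (59 and 40), without the 3 libraries (2 and 0), with library weights (63 and 56), at a mean RPKM of at least 2 (14 and 12), and without control replicate 1 (6 and 3), 2 h replicate 1 (4 and 3) or 6 h replicate 2 (3 and 1). All 19 had groups that did not overlap, as did 22.6% of all genes (10% by chance).

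Between the times, 30 genes were called against control in the same direction at both, 20 higher and 10 lower, and Neat1 in opposite directions. Shared genes included Foxo1, Pik3ip1, Inmt, Acvr1b, Cry2, Hes1, Dusp10 and Ccdc69. Independent lists of these sizes would share 0.63 higher and 0.24 lower genes, and unchanged groups simulated against the same controls shared a mean of 0.01 and at most 1. Both values treat each gene on its own. They lack differences between libraries that many genes share, such as the first principal component, so they are too low a bar for the 30. The log2 fold changes correlated across genes at r = 0.56, against 0.50 simulated, with a covariance of 0.07 against 0.03 simulated. The 3 controls could not be split into parts of at least 2 libraries. Part of the excess may come from sharing controls that differ in ways the simulation lacks. The shared count of 30 was 0 without control replicate 2, control replicate 3 or 2 h replicate 2, 10 without 2 h replicate 1, 3 without 2 h replicate 3, 7 without 6 h replicate 1, 5 without 6 h replicate 3, 53 without control replicate 1 and 124 without 6 h replicate 2; edgeR gave 55 and DESeq2 391. The split of 20 higher and 10 lower turned with the scaling, the tool or the libraries: equal medians gave 14 and 18, quantile normalization 15 and 20, edgeR 23 and 32, DESeq2 176 and 215, and leaving out control replicate 1, 6 h replicate 2 or 2 h replicate 3 gave 19 and 34, 60 and 64, or 1 and 2. Tfrc stood at log2 -0.91 at 6 h and was not called there; its difference between the times was not called either.

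**Figure D3:**
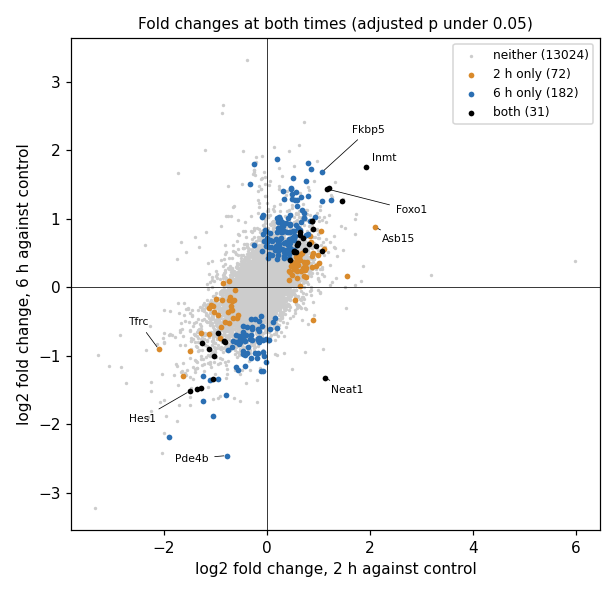
Log2 fold change at 6 h against that at 2 h, both relative to control, for each tested gene; colours mark genes called at neither time, at 2 h only (72), at 6 h only (182) or at both (31). Most genes called at both times lie in the same direction, and Neat1 lies in the lower right.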

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

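The tests of depth, of macrophage and fibroblast RNA, of the muscle share and of hypoxia in every animal at 2 h, and the fits without the 3 libraries or with a term for them, were chosen only after the result was seen.

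The 2 h and 6 h groups differed for 19 genes by the limma test of the difference itself. With a single control group, hours of exposure cannot be told apart from clock time or handling. Neat1 differed by -2.45 on the log2 scale, going from 1.13 at 2 h to -1.32 at 6 h against control. Other genes lower at 6 h than at 2 h included D4Wsu53e (-1.39), Tmem100 (-1.14), B3galnt2 (-1.09), Gm16983 (-0.80), Clec2d (-0.74), Gm17345 (-0.66), Mettl3 (-0.64) and Actr6 (-0.61). The genes higher at 6 h were 6430548M08Rik (2.04), Mtss1 (1.13), Amotl2 (1.08), Fam117b (0.87), Abhd1 (0.85), Jup (0.83), Pitx3 (0.77), Tpst2 (0.72) and Acsl1 (0.69). Gm16983, Gm17345, 6430548M08Rik, B3galnt2, Mettl3 and Abhd1 each overlap another annotated gene. Of the 10 splits of the 6 hypoxia libraries, 1 gave as many genes, the real one with 19, and the highest other gave 0; 10 splits are too few for a share under 0.05.

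Matrix and macrophage genes were high in control replicates 2 and 3 and 6 h replicate 2. Depth is weakly argued against as the source, since all 3 libraries lay inside the depth range of the other 6. The low end of that range rests on 6 h replicate 3 alone, and control replicate 2 and 6 h replicate 2 were the next shallowest. The shallowest library, 6 h replicate 3, had no high matrix genes (list mean -0.503 on the log2 scale). A swap of the labels of control replicate 1 and 6 h replicate 2 is argued against by 200 genes. These were chosen between 6 h replicates 1 and 3 and control replicate 1. In 6 h replicate 2 against control replicates 2 and 3, 86% of them kept their sign, against 69.5% of all genes. A lower share of muscle RNA would raise every other cell type alike, yet endothelial markers differed by 0.119 and macrophage markers by 1.53 on the log2 scale. Of 23 tested macrophage and fibroblast markers 82.6% were higher in each of the 3 libraries than in each of the other 6, which restates the pattern and tests no source. RNA from such cells and a different dissection stay open, and no biological explanation was tested.

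Genes of the choroid plexus, the brain tissue that makes cerebrospinal fluid, were high in 2 h replicate 2, where Ttr stood at 1494, Enpp2 at 190, Folr1 at 19.6, Igfbp2 at 16.7 and Kcnj13, which overlaps Gigyf2, at 8.22 RPKM. Of 21 other markers of this tissue listed before the test, 76.2% had their highest value there, although muscle also expresses some of them, such as Aqp1. The lowest peak of any gene in the deposited data was 0.7319 RPKM. Some markers, such as Tmem72 (1.38 RPKM there and 0.0464 in every other library), are thus present only through this library. The share of 76.2% is therefore partly fixed in advance. Of 6 neuron and astrocyte markers 0% were highest there. That share is a weak test of brain tissue at large. Camk2a, Aqp4 and Stmn2 are well expressed in every library, and the other 3 peaked in 2 h replicate 3. Snap25, Nrgn and Slc1a3 stood at 0.208, 0.455 and 0.745 RPKM in 2 h replicate 2, inside their range in the controls. This argues against much RNA from brain at large in this library. The median of all 26 choroid plexus markers argues against a rise of similar size in every animal after 2 h of hypoxia. It lay 2.21 above the control mean on the log2 scale in 2 h replicate 2 but -0.005 and 0.033 from it in replicates 1 and 3. The limit given for the 76.2% also holds for the 2.21. A smaller rise is not excluded, since markers far below the pseudocount of 0.5 barely move this median. In 2 h replicate 1, 2 of the 5 genes noticed first lay above all controls. Ttr was 1 of them, at 0.773 RPKM against at most 0.086 RPKM in the controls. In 2 h replicate 3 the 5 genes noticed first still lay above all controls (Ttr 21.1, Enpp2 7.98, Igfbp2 0.361, Folr1 0.319 and Kcnj13 0.184 RPKM), 3 of the 6 neuron and astrocyte markers were at their highest (Snap25 2.69, Nrgn 1.65 and Slc1a3 1.22 RPKM), and the source of these was not tested. RNA or reads from choroid plexus may be the source in 2 h replicate 2, and how they came there was not tested.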

How the results depend on the processing

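The fits without the 3 libraries of high matrix genes, with a term for them, with edgeR and with DESeq2, and the list tests without single libraries, were chosen only after the data were seen. Counts are given for 2 h against control, 6 h against control, 6 h against 2 h and both times, where the reported values were 103, 213, 19 and 30. Leaving out 1 library at a time gave 0 to 396, 10 to 417, 0 to 9 and 0 to 124. Without the mean-variance trend they were 29, 186, 6 and 15, with library weights, which gave control replicate 3 a weight of 8.24, 3068, 4113, 119 and 1785, and with only the groups compared 124, 73, 3 and 12. A mean RPKM of at least 2 gave 199, 202, 26 and 40, and equal medians 125, 242, 51 and 32. Without the 3 libraries the counts were 0, 0, 2 and 0, with 1578, 1649 and 1953 genes at unadjusted p under 0.05 by limma; this leaves 1 control, assumed to vary like the other groups. With the term they were 6, 374, 99 and 4; the term was chosen from the data, so its p-values are too small. Reads gave 186, 329, 64 and 55 with edgeR and 1406, 1128, 891 and 391 with DESeq2. The cause of these shifts was not tested, apart from the fewer libraries or genes in some fits. Other pseudocounts, no filter, quantile normalization and a threshold of 1.5-fold moved no count by more than 1.5 times.

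With the replicate number as a block the counts were 1, 43, 2 and 1. The numbers showed no general pairing of the libraries: 2 of 9 pairs with the same number correlated above 0.1, over a range of -0.331 to 0.493. The highest pair, control replicate 2 with 6 h replicate 2, joins libraries of high matrix genes. That pattern may hide a weaker pairing, which is not excluded.

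Of 30 list calls at the preset correlation, 0 held with an estimated one. Immediate early genes at 2 h turned from lower to higher without the 3 libraries, with a signed negative log10 p of 0.437 (camera adjusted p = 0.568); the cause was not tested. Of the 26, 37 and 19 called genes followed singly in these comparisons, 3, 36 and 19 stayed called with the term and 26, 33 and 17 with edgeR. Each called gene kept its sign in every limma setting that tested it. Since the groups of each called gene did not overlap, only the rescalings and the term could have turned a sign. The depth of 72706716 reads in 6 h replicate 3, the lowest, limits low genes in that library most.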

Other observations

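The tests of Cirbp and Rbm3 and the fits with a term for the 3 libraries of high matrix genes were chosen only after the result was seen.

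Among genes not described above, Robo4, a guidance receptor of endothelial cells, rose at 6 h (log2 0.81), Trp53inp1, a p53 target, rose (0.78), and Pdgfa, a platelet-derived growth factor, fell by 0.87 on the log2 scale, each past the limma test.

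Heat shock genes had lower means under hypoxia at both times, with medians of -0.76 and -0.471, and were high in control replicates 2 and 3 and 6 h replicate 2. With a term for these 3 libraries the medians were -0.266 and -0.314, and 15 of 18 members lay below 0 at 6 h, so the libraries may hold part of the difference, and how much cannot be told apart from the exposure, since that value lies between the bounds set for both outcomes. For a lower body temperature, the cold-induced genes Cirbp and Rbm3 had a mean log2 of 0.834 (0.146 SE) at 6 h. That SE takes the 2 genes as independent and is too small if they vary together between libraries. At 2 h Cirbp and Rbm3 stood at 0.59 and -0.27, neither called, and the cold-inducible list had a median of -0.128 (camera adjusted p = 0.905). Temperature cannot be told apart from the exposure itself, which goes with it, and the labels give no temperature.

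At 2 h against control 103 genes were called and the highest other split gave 2, with 1 of 10 splits as large. At 6 h against control 213 were called and 2 of 10 splits gave as many. The other one, which sets control replicate 1 and 6 h replicates 1 and 3 against control replicates 2 and 3 and 6 h replicate 2, called 958 genes, which points to a structure of the samples that the groups do not follow. In both cases 10 splits are too few for a share under 0.05. For the 30 genes called at both times, 2 of 100 regroupings of the 9 libraries gave as many, the real one included, a share under 0.05. The other regrouping gave 631, which again points to a structure of the samples. Libraries with such a structure are not interchangeable, so this share cannot exclude chance for the 30 and does not measure a response to hypoxia. For the 30 list calls at the preset correlation, 58 of 100 regroupings gave as many, with up to 48, so chance is not excluded for the list calls.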
